A study of Homo sapiens with 12 samples.

How the data were processed

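The libraries were made from messenger RNA of A549 and NCI-H460 cells, established human non-small cell lung cancer lines, with 3 libraries in each of 4 groups. Each line received vehicle or 0.1 µM GSK3326595, an inhibitor of the arginine methyltransferase PRMT5, for 48 h. The labels give the line and treatment of every library. Nothing in the labels says that equally numbered libraries share a culture or a day, or that the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

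The authors deposited a table of raw counts per gene, in whole numbers that had not been normalized. Per the labels' protocols, total RNA was purified with a column kit and libraries were made with a SMARTER mRNA-seq kit. The submitters' processing notes name the mouse builds GRCm38 and mm10, whereas the table carries human gene symbols and Ensembl identifiers. The build is therefore not settled and no coordinates are given. The aligner, the counting tool and the use of strand are not given in the sources used here. Counts of antisense and overlapping genes are uncertain for that reason, as are those of genes with near-identical copies, such as ribosomal protein, HLA and AKR1 genes.

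The table holds 62811 genes, of which 22460 carry only an Ensembl identifier and 29364 have no count in any library. It has no summary rows. Totals ran from 15050804 to 16996850 counts per library. The 16153 genes kept by the edgeR expression filter held nearly all counts. Libraries of each group were compared in pairs by chi-square over genes, and every pair differed by more than sampling noise, so none was treated as a duplicate. Intervals and floors cover counting error only.

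Differential expression was tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 with robust fitting, TMM scaling and Benjamini-Hochberg adjustment at 0.05. All 12 libraries entered 1 model with 4 groups, which left 8 residual degrees of freedom and a common biological coefficient of variation of 0.0594. Its contrasts were treatment in A549, treatment in H460, the A549 effect minus the H460 effect, and vehicle A549 against vehicle H460. Errors of log2 fold changes are approximate standard errors, computed as the absolute log2 fold change divided by the square root of the F statistic. Levels are CPM, counts scaled to a common TMM-adjusted library size, given as mean ± SD. A group at 0 was set to a floor of 3 counts per library. Overlap of calls was tested with Fisher's exact test.

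Gene lists were fixed before the data were examined. There were 32 lists, and the 30 with at least 5 tested members were tested with camera of limma 3.58.1 on voom values with a preset correlation of 0.01. Each was also tested with an estimated correlation and with fry. Genes named for each treatment contrast are the 10 highest and 10 lowest log2 fold changes among genes with an adjusted p under 0.05, at least 10 CPM in the higher group and no overlap between libraries. For the difference and the vehicle comparison 6 in each direction were taken, without the overlap condition for the difference. Clone names, pseudogenes and unnamed identifiers were skipped. A set of genes tied to PRMT5, p53, NNMT and LKB1 was tested in every contrast, and up to 4 members of smallest p were taken from each called list. Some genes under this rule are not reported here.

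The fitting steps were tested on counts simulated from the real means, library sizes and dispersion with 200 changed genes. In the simulated A549 comparison on 15821 genes, 82.1% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 2.67% of calls were false. In the simulated H460 comparison on 15833 genes the shares were 73.1%, 91.0% and 100%, with 2.76% false. For the difference, changes of 1.5-fold were recovered in 59.7% of genes changed in A549 and 58.2% of genes changed in H460, with 1.94% and 5.36% of calls false. A p53 list raised 1.5-fold was called in both lines, along with 1 of 29 other lists. The simulated genes were drawn independently of each other. False calls of lists under correlation between genes were therefore not measured. Other groupings of the 6 libraries of a line called up to 10 lists in A549 and up to 12 in H460. The real labels gave 8 and 14. Those other groupings called at most 1 gene in A549 and 0 in H460. They mixed treated and vehicle libraries and kept part of the treatment effect, so they give no rate of false calls. In A549 the number of lists called with the preset correlation therefore does not set the real labels apart.

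The alternatives planned together with the lists were DESeq2 size factors, no count filter, a filter of 10 CPM in 3 libraries, DESeq2 1.42.0, limma voom, a fit of only the 6 libraries compared, the replicate number as a block, leaving out each library, an adjusted p under 0.01 and an absolute log2 fold change of at least 1. Chosen after seeing the data were removal of each library's GC trend, a restriction to genes expressed in the line, and p53 and replication lists without members shared with other lists. GC content came from GENCODE transcripts matched by symbol. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.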

Results

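Gene expression was profiled by mRNA sequencing in A549 and H460 cells after 48 h with vehicle or 0.1 µM GSK3326595, an inhibitor of PRMT5, which symmetrically dimethylates arginines in spliceosomal and other proteins. The series asked why lung cancer cells grow more slowly under PRMT5 inhibition, with LKB1 loss and NNMT named in its title. Each of the 4 groups had 3 libraries, and the 12 totals lay between 15050804 and 16996850 counts. The line accounted for most of the variance, with 90.2% on the first principal component, and treatment separated on the second with 2.45%. Mitochondrially encoded transcripts took 4.91% of counts in H460 vehicle replicate 3 and between 1.73% and 3.32% in the other libraries.

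In A549, treatment raised p53 target genes, while the mitosis and DNA replication lists were called lower with the preset correlation but not with an estimated one (adjusted p = 0.145 and 0.366). Of 29 p53 targets tested, 20 rose and none fell, among them MDM2, a ubiquitin ligase, from 94.8 ± 1.75 to 149 ± 7.01 CPM (n = 3; log2 fold change 0.66 ± 0.05, edgeR adjusted p = 2.49e-13). CDKN1A, the cell cycle inhibitor p21, rose from 149.8 ± 11.3 to 208 ± 8.59 CPM, BAX by 0.40, CCNG1 by 0.49 and POLH by 0.61 on the log2 scale. The list was called higher by limma camera (adjusted p = 2.31e-19, and adjusted p = 0.0135 with an estimated correlation). Adjusted over the list alone, 23 members rose.

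Of 32 mitosis genes in A549, 16 fell and 1 rose. TOP2A, a DNA topoisomerase of dividing cells, went from 588 ± 15.2 to 406 ± 19.6 CPM, and CENPA fell by 0.59, AURKB by 0.49 and KIF20A by 0.41 on the log2 scale. The limma camera adjusted p was 1.70e-08, and the adjusted p = 0.145 with an estimated correlation. Among 38 replication genes 11 fell and 1 rose, with GINS4 down by 0.64, POLA1 by 0.55, LIG1 by 0.41 and TK1 by 0.36 (camera adjusted p = 0.000452, and adjusted p = 0.366 with an estimated correlation). Of 23 homologous recombination and Fanconi genes, 9 fell and 2 rose, with FANCI down by 0.45 and FANCD2 by 0.45 (camera adjusted p = 0.00363, and adjusted p = 0.334 with an estimated correlation). By p-values adjusted over the list alone, 19 mitosis, 12 replication and 11 recombination and Fanconi genes fell.

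The spliceosome and ribosome lists were called higher in A549 with the preset correlation but not with an estimated one. Of 35 core spliceosome genes 17 rose and none fell, including PRPF3 by 0.53, PRPF6 by 0.32, SF3A2 by 0.30 and SNRNP200 by 0.27 on the log2 scale (limma camera adjusted p = 3.85e-07, and adjusted p = 0.172 with an estimated correlation). Ribosomal protein genes rose in 16 of 42 cases, with RPL22 up by 0.45 and RPL4 by 0.28 (camera adjusted p = 7.42e-09, adjusted p = 0.469 with an estimated correlation and 0.0761 with fry). Ribosome biogenesis genes rose in 10 of 21 cases, PES1 by 0.40 and NPM1 by 0.27, while NOP56 fell by 0.26 (camera adjusted p = 2.63e-05, and adjusted p = 0.145 with an estimated correlation). NRF2 targets, which encode antioxidant enzymes, rose in 11 of 23 cases and fell in 1, with TXNRD1 up by 0.52, OSGIN1 by 0.51 and SRXN1 by 0.48 (camera adjusted p = 6.11e-07, and adjusted p = 0.301 with an estimated correlation). Adjusted over the list alone, 19 spliceosome, 21 ribosomal protein, 12 ribosome biogenesis and 11 NRF2 genes rose.

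The highest log2 fold changes by the fixed rule in A549 were those of PLEKHG6 at 1.12, ATP6V0C at 0.96, MAP2 at 0.91, RPL17 at 0.91, KRT4 at 0.84, GFRA1 at 0.83, CHML at 0.81, GRIN2B at 0.81, SNHG3 at 0.79 and MAP3K14, the kinase NIK, at 0.79. RPL17 may share reads with copies of the gene. The lowest were OPLAH at -1.33, NEAT1 at -1.11, CRYL1 at -1.10, NPTX1 at -1.06, COL5A1 at -1.04, PSMG3-AS1 at -0.999, ACP2 at -0.97, GGCX at -0.96, FSTL4 at -0.94 and COL1A1 at -0.94. The fibrillar collagen COL5A1 went from 76.3 ± 4.87 to 37.2 ± 3.51 CPM. The edgeR call of NEAT1 (adjusted p = 0.0283) was lost without A549 vehicle replicate 2 or 3 or A549 treated replicate 1 or 2, at adjusted p = 0.0915, 0.0994, 0.0964 and 0.0781. It was also lost with no count filter and with the 6 A549 libraries alone. These fits had no block for the replicate number. NEAT1 rose with that number in both groups, at 318, 500 and 552 CPM with vehicle and 152, 221 and 260 CPM with treatment.

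PRMT5 rose by 0.18 ± 0.06 in A549 (edgeR adjusted p = 0.0295), a call lost with limma voom (adjusted p = 0.0512) and without A549 vehicle replicate 2 or 3 or treated replicate 1 or 2, at adjusted p between 0.0763 and 0.181. NNMT, nicotinamide N-methyltransferase, had 121 ± 8.89 CPM with vehicle and 140.4 ± 3.60 with treatment (log2 fold change 0.22, edgeR adjusted p = 0.0129), and its call was lost without vehicle replicate 2 or 3 or treated replicate 2 or 3 (adjusted p between 0.0532 and 0.0743). CCND1, cyclin D1, rose by 0.35. Log2 fold changes that did not pass the test were -0.06 for WDR77, 0.12 for MDM4, -0.19 for MAT2A, 0.13 for MYC, -0.05 for STK11, which encodes LKB1, -0.01 for E2F1, -0.06 for KAT5, -0.16 for MTAP and -0.03 for CD274. MTAP and CD274 had 20 and 30 counts over the 3 vehicle libraries. MYC passed without A549 vehicle replicate 1 (edgeR adjusted p = 0.0172) and with the GC trend removed (0.0276). MAT2A passed without H460 vehicle replicate 3 (edgeR adjusted p = 0.0216), with no count filter (0.0115) and with the 6 A549 libraries alone (0.00398).

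In all, 1398 genes were higher and 1455 lower in treated A549 by edgeR's quasi-likelihood test, of which 41 and 97 changed at least 2-fold. Treated and vehicle libraries did not overlap for 94.4% of the called genes and 31.8% of all tested genes, against 10% by chance. The other 22 tested lists were not called, among them the PRMT family (limma camera adjusted p = 0.536), methionine, NNMT and polyamine metabolism (adjusted p = 0.397) and LKB1 and AMPK-related kinases (adjusted p = 0.663). The PRMT list's median and mean log2 fold change differed in sign, at 0.06 and -0.14, as did those of the methionine and NNMT list, at 0.02 and -0.02.

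In H460, treatment raised p53 targets and inflammatory genes and lowered DNA replication genes. Of 29 p53 targets 23 rose and none fell. CDKN1A went from 89.5 ± 5.93 to 234 ± 25.7 CPM (n = 3; log2 fold change 1.39 ± 0.07, edgeR adjusted p = 8.17e-14), MDM2 from 106 ± 3.48 to 234 ± 7.97 CPM, and GDF15, a secreted stress cytokine, from 40.4 ± 2.51 to 142 ± 23.8 CPM. BTG2 rose by 1.51, ZMAT3 by 1.04 and RRM2B by 0.87 on the log2 scale. The limma camera adjusted p of the list was 4.05e-24, and the adjusted p = 0.00769 with an estimated correlation. By p-values adjusted over the list alone, 25 rose.

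Replication genes fell in 27 of 38 cases in H460 and none rose. GINS4, a subunit of the replicative helicase, went from 31.8 ± 1.32 to 12.6 ± 0.441 CPM, RRM2, a ribonucleotide reductase subunit, from 485 ± 27.5 to 267 ± 5.98 CPM, and POLA1 and TK1 fell by 0.76 and 0.58 on the log2 scale. The limma camera adjusted p was 1.49e-17, and the adjusted p = 0.0329 with an estimated correlation. Homologous recombination and Fanconi genes fell in 15 of 23 cases and rose in 1, with BARD1 down by 0.82, FANCA by 0.80, FANCI by 0.77 and BRCA1 by 0.65 (camera adjusted p = 5.48e-08, and adjusted p = 0.0995 with an estimated correlation). Of 32 mitosis genes 15 fell and 2 rose, with FOXM1 down by 0.59, CENPA by 0.65 and TOP2A by 0.52 (camera adjusted p = 2.24e-05, and adjusted p = 0.212 with an estimated correlation). Adjusted over the list alone, 30 replication, 16 recombination and Fanconi and 16 mitosis genes fell.

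Among 19 NF-kB and inflammatory genes in H460, 11 rose and 1 fell. BIRC3 rose by 0.73, the chemokine CXCL5 by 0.54, NFKB2 by 0.47 and TNFAIP3 by 0.46 on the log2 scale (limma camera adjusted p = 3.39e-05, and adjusted p = 0.0172 with an estimated correlation). RAS-MAPK output genes rose in 7 of 16 cases and fell in 1, with PHLDA1 up by 0.51 and the phosphatase DUSP4 by 0.40 (camera adjusted p = 0.00687, and adjusted p = 0.437 with an estimated correlation). Core spliceosome genes rose in 9 of 35 cases and fell in 1, with PRPF3 up by 0.87 and SF3B1 by 0.44 (camera adjusted p = 0.00687, and adjusted p = 0.492 with an estimated correlation). SR protein and hnRNP genes rose in 10 of 25 cases and fell in 2, with HNRNPH1 up by 0.33 and HNRNPA2B1 by 0.30, while HNRNPF fell by 0.22 (camera adjusted p = 0.0119, adjusted p = 0.553 with an estimated correlation and 0.0524 with the GC trend removed). By p-values adjusted over the list alone, 11 inflammatory, 8 RAS-MAPK, 11 spliceosome and 12 SR and hnRNP genes rose.

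Antigen presentation genes fell in 6 of 11 cases in H460, HLA-C by 0.47 and HLA-B by 0.45 on the log2 scale, although reads of these related genes may be shared (limma camera adjusted p = 0.0101, and adjusted p = 0.271 with an estimated correlation). Apoptosis regulators rose in 8 of 24 cases, PMAIP1 by 0.61, BAX by 0.54 and TNFRSF10B by 0.37, and fell in 2, including the anti-apoptotic MCL1 by 0.31 (camera adjusted p = 0.0274, adjusted p = 0.203 with an estimated correlation and 0.0526 without H460 vehicle replicate 3). BAX, BBC3 and TNFRSF10B also stand in the p53 list, and the apoptosis list was not tested without them. Cholesterol genes fell in 7 of 23 cases and rose in 2, with MVD down by 0.77 and IDI1 by 0.39 (camera adjusted p = 0.0231, adjusted p = 0.614 with an estimated correlation, 0.270 without vehicle replicate 2 and 0.0624 without treated replicate 1). Glycolysis and hypoxia genes fell in 7 of 22 cases and rose in 1, with ADM down by 0.79 and PFKL by 0.36 (camera adjusted p = 0.0269, adjusted p = 0.614 with an estimated correlation, 0.0948 with fry, 0.220 with the GC trend removed, 0.457 without vehicle replicate 2 and 0.145 without treated replicate 1). Oxidative phosphorylation genes rose in 8 of 33 cases and fell in 3, with ATP5PB up by 0.31 (camera adjusted p = 0.0123, adjusted p = 0.614 with an estimated correlation and 0.0948 with fry). Ribosomal protein genes rose in 4 of 42 cases, RPL34 by 0.19, and RPS14 fell by 0.28 (camera adjusted p = 0.0188, adjusted p = 0.743 with an estimated correlation, 0.336 with fry, 0.447 without vehicle replicate 3 and 0.193 without treated replicate 3). Of all 16153 tested genes 2071 were called higher in H460, so the share of ribosomal protein genes called higher was no larger. The edgeR call of RPL34 was lost without vehicle replicate 3 (adjusted p = 0.0540). Adjusted over the list alone, 6 antigen presentation, 7 cholesterol and 7 glycolysis genes fell, and 8 apoptosis, 8 oxidative phosphorylation and 2 ribosomal protein genes rose.

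By the fixed rule, the highest log2 fold changes in H460 were those of GDF15 at 1.82, the asparagine synthetase gene ASNS at 1.78, BTG2, CDKN1A, SULF2 at 1.28, GREB1 at 1.22, HAPLN3 at 1.20, MDM2, the splicing regulator PTBP2 at 1.12 and SH2D2A at 1.10. The lowest were SFXN2 at -1.82, the nuclear RNA NEAT1 at -1.61, complement C3 at -1.38, GINS4, ACP2 at -1.30, CRYL1 at -1.30, DCAF16 at -1.28, HGH1 at -1.27, MUC1 at -1.27 and GLB1L at -1.19. CD274, which encodes PD-L1, rose from 19.2 ± 1.65 to 31.4 ± 2.20 CPM. MYC fell by 0.22, E2F1 fell by 0.36 and MDM4 rose by 0.25. The edgeR call of MDM4 was lost without H460 vehicle replicate 3 (adjusted p = 0.0647).

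NNMT was near the detection limit in H460, at 1.58 ± 0.652 CPM with vehicle and 0.911 ± 0.160 with treatment (log2 fold change -0.78 ± 0.28, edgeR adjusted p = 0.0308). That call was lost without H460 vehicle replicate 1 or 3 or treated replicate 1 or 3 (adjusted p between 0.0630 and 0.318), with limma voom (0.225) and with the 6 H460 libraries alone (0.119). PRMT5 had a log2 fold change of 0.15 (adjusted p = 0.0579), and it passed in 13 of the alternatives. MAT2A had -0.31 (adjusted p = 0.0749), and passed with DESeq2, limma voom and no count filter and without H460 vehicle replicate 2 or 3 or treated replicate 1. Log2 fold changes that did not pass were -0.06 for WDR77, -0.26 for KAT5, -0.11 for MTAP, -0.06 for STK11 and 0.01 for CCND1.

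Altogether 2071 genes were higher and 2251 lower in treated H460 by edgeR's quasi-likelihood test, of which 170 and 197 changed at least 2-fold. Treated and vehicle libraries did not overlap for 94.7% of called genes and 39.4% of all tested genes. In A549, 46 called genes lay under 1 CPM in both A549 groups, and 105 in H460 did so, all with at least a 2-fold change, so large folds rest on few counts in these cases. The other 16 tested lists were not called, among them the PRMT family (limma camera adjusted p = 0.867), methionine, NNMT and polyamine metabolism (adjusted p = 0.649) and LKB1 and AMPK-related kinases (adjusted p = 0.680). Camera ranked the PRMT list up while its median was -0.04, and the LKB1 list had a median of -0.02 and a mean of 0.01.

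**Figure D1:**
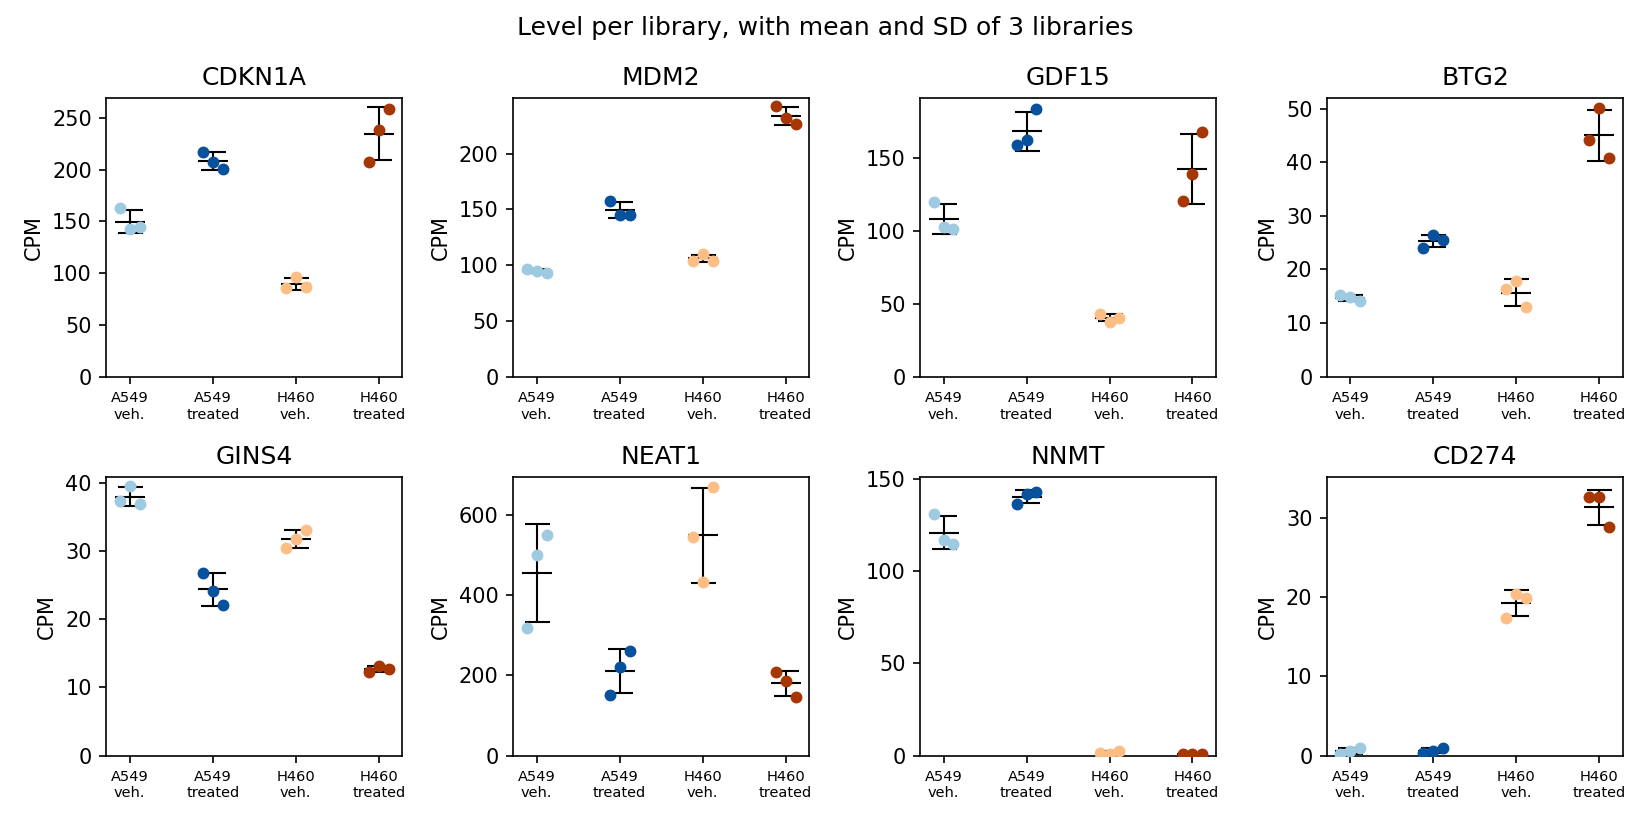
Level in CPM of 8 genes in each library (points) with the mean and SD of 3 libraries (lines), for vehicle and treated A549 and H460. CDKN1A, MDM2, GDF15 and BTG2 were higher and GINS4 lower in all treated libraries of both lines, and NNMT was at 121 CPM in vehicle A549 and 1.58 CPM in vehicle H460.

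The same genes changed in both lines more often than independent calls would give. Of 16153 genes, 667 were higher in both, against 179 for independent lists (Fisher's exact odds ratio 8.67, 95% interval 7.69 to 9.79, p = 1.28e-254), and 760 were lower in both, against 203 (odds ratio 9.68, p = 2.54e-302). Opposite changes were found for 70 genes higher in A549 and lower in H460 and for 48 the other way. MDM2, CDKN1A, BTG2, GDF15, PRPF3 and TXNRD1 were higher in both, and GINS4, POLA1, TOP2A, CENPA, ACP2 and CRYL1 lower in both. Across the 1545 genes called in both, Pearson's r of the log2 fold changes was 0.700 and Spearman's rho 0.809, over genes, which are not independent replicates. Selection by both calls raises these values, and over the 5630 genes called in either line they were 0.385 and 0.548, and over all tested genes 0.201 and 0.333. The change was larger in H460 for 59.2% of the genes called in both.

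**Figure D2:**
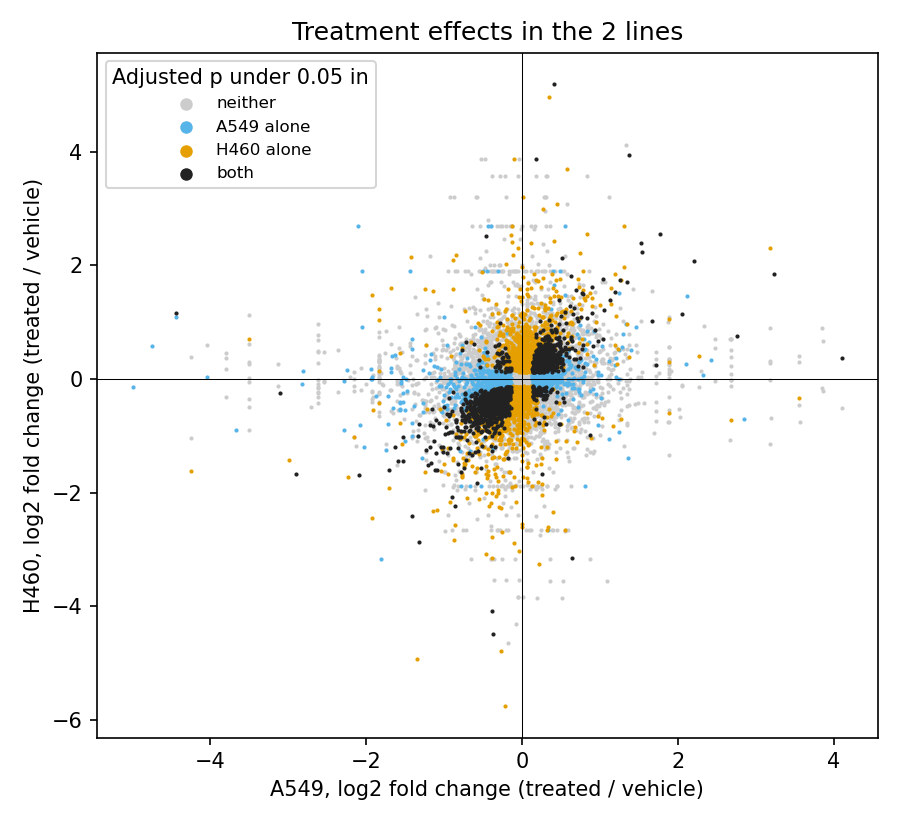
Log2 fold change (treated over vehicle) in H460 against that in A549 for the 16153 tested genes, coloured by the lines in which the edgeR adjusted p was under 0.05. Genes called in both lie mainly in the quadrants of equal direction, with 667 higher and 760 lower in both.

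In the test of the difference itself, the p53 and replication lists were called with the preset correlation but not with an estimated one (adjusted p = 0.133 for each). CDKN1A rose less in A549, with a difference of -0.91 ± 0.10 on the log2 scale (edgeR adjusted p = 5.97e-07), as did MDM2 at -0.48, ZMAT3 at -0.70 and RRM2B at -0.50. Of 29 p53 targets 11 differed, all with the smaller rise in A549 (limma camera adjusted p = 4.62e-09, and adjusted p = 0.133 with an estimated correlation). Replication genes differed in 11 of 38 cases, RRM2 by 0.63, GINS4 by 0.69, TYMS by 0.53 and FEN1 by 0.49 (camera adjusted p = 5.71e-12, and adjusted p = 0.133 with an estimated correlation). TYMS rose by 0.26 in A549 (edgeR adjusted p = 0.00916) and fell by 0.28 in H460, and FEN1 did not pass in A549 at -0.03. Homologous recombination and Fanconi genes differed in 5 of 23 cases, BRCA1 by 0.40 and FANCI by 0.32 (camera adjusted p = 7.88e-05, and adjusted p = 0.229 with an estimated correlation). By p-values adjusted over the list alone, 11 p53 targets, 14 replication and 8 recombination and Fanconi genes differed.

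Ribosome biogenesis genes had the higher effect in A549 in 6 of 21 cases, with MYC at 0.35, GNL3 at 0.40 and BOP1 at 0.34 (limma camera adjusted p = 1.47e-05, and adjusted p = 0.137 with an estimated correlation). Glycolysis and hypoxia genes did so in 4 of 22 cases and had the lower effect in 1 (PDK1 at -0.48), with ADM at 1.27 and HK1 at 0.33 (camera adjusted p = 4.58e-05, adjusted p = 0.415 with an estimated correlation and 0.0695 with fry). Cholesterol genes did so in 4 of 23, HMGCS1 at 0.50 and IDI1 at 0.42 (camera adjusted p = 0.00486, adjusted p = 0.591 with an estimated correlation, 0.162 with fry and 0.0725 without H460 vehicle replicate 2). NRF2 targets did so in 5 of 23 and had the lower effect in 1 (AKR1B10 at -0.28), with OSGIN1 at 0.55 and SRXN1 at 0.53 (camera adjusted p = 0.0199, adjusted p = 0.692 with an estimated correlation and 0.270 with fry). That NRF2 call was lost without H460 vehicle replicate 2 (adjusted p = 0.0725), A549 vehicle replicate 2 (0.0753) or 3 (0.136), or A549 treated replicate 1 (0.0726). Ribosomal proteins did so in 1 of 42, RPL22 at 0.38 (camera adjusted p = 0.00486, adjusted p = 0.901 with an estimated correlation and 0.545 with fry). The ribosomal protein call was lost without H460 vehicle replicate 2 (0.419), A549 vehicle replicate 2 (0.0535) or 3 (0.0692), or A549 treated replicate 1 (0.113). Of all 16153 tested genes 677 had the higher effect in A549, so the share of ribosomal protein genes was no larger.

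Matrix genes had the lower effect in A549 in 6 of 26 cases and the higher in 2, COL5A1 at -0.91 and TGFBI at -0.51 (limma camera adjusted p = 0.00486, and adjusted p = 0.229 with an estimated correlation). Inflammatory genes had the lower effect in A549 in 4 of 19, CXCL2 at -0.62 and CXCL5 at -0.56, and the higher in 1, TNFAIP2 at 0.39 (camera adjusted p = 0.0197, and adjusted p = 0.137 with an estimated correlation). CCND1 differed by 0.33 and E2F1 by 0.35. NNMT differed by 0.996 (edgeR adjusted p = 0.0202), on few H460 counts, and lost its call with limma voom (0.216) and without H460 vehicle replicate 1 (0.0514), vehicle replicate 3 (0.221) or treated replicate 3 (0.0887). Differences that did not pass were 0.03 for PRMT5, 0.01 for WDR77, -0.14 for MDM4, 0.12 for MAT2A, -0.05 for MTAP, 0.01 for STK11, 0.21 for KAT5 and -0.73 for CD274.

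In the difference, 677 genes were higher and 552 lower by edgeR's quasi-likelihood test. The fixed rule named FGA, CEACAM19, CD38, ADM, SFXN2 and LSR as highest and CES1, SYT13, PAK3, SUSD2, LINC01234 and PAX6 as lowest. Most of these rest on few counts in 1 line. Single H460 libraries had 0 to 10 counts of SYT13, 1 to 12 of SUSD2, 2 to 20 of CEACAM19, 3 to 20 of CD38 and 10 to 28 of LSR. Single A549 libraries had 6 to 29 counts of PAX6. FGA had 12 counts in vehicle and 1 in treated H460 (ratio 0.0856, 95% exact binomial interval 0.0020 to 0.578), and PAK3 had 12 and 1 in A549 (ratio 0.0876, interval 0.0020 to 0.592). CES1 had 0 counts in vehicle and 13 in treated H460, so its fitted difference depends on the prior count and is no bound. The edgeR call of CES1 was lost without H460 vehicle replicate 1, 2 or 3 or treated replicate 3 (adjusted p = 0.0662, 0.0619, 0.0538 and 0.0583). That of SUSD2 was lost without H460 vehicle replicate 1 or 3 or treated replicate 2 or 3 (0.142, 0.0981, 0.152 and 0.136). That of PAK3 was lost without H460 vehicle replicate 3 (0.0513), treated replicate 1 (0.0525) or 2 (0.0557), A549 vehicle replicate 1 (0.0666), 2 (0.0788) or 3 (0.0743), or A549 treated replicate 1 (0.173) or 3 (0.165). With limma voom, the adjusted p was 0.0685 for CEACAM19, 0.0556 for CES1 and 0.286 for SUSD2. That of PAK3 was also lost with DESeq2 (adjusted p = 0.0903) and with no count filter (0.0762). No list kept its call with an estimated correlation, and the other 20 tested lists were not called.

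**Figure D3:**
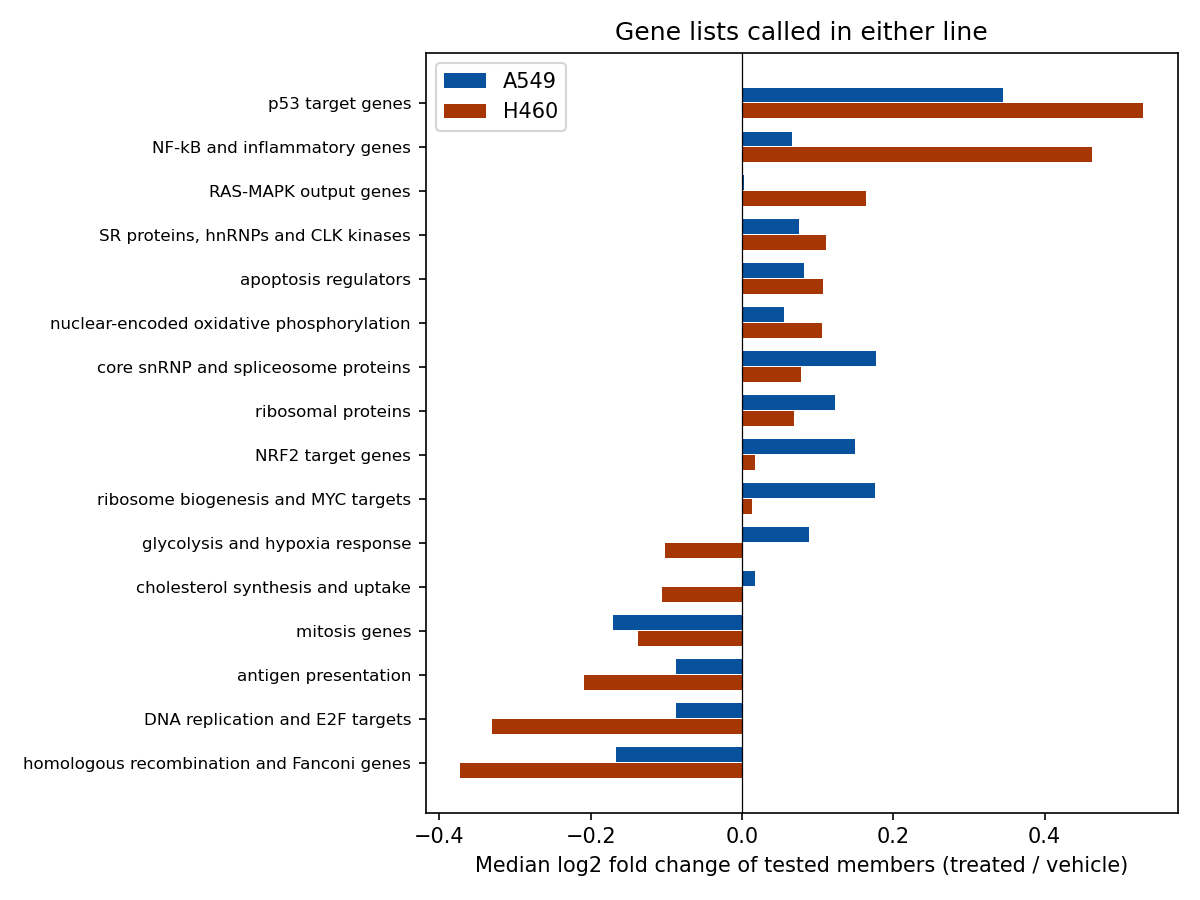
Median log2 fold change (treated over vehicle) of the tested members of each gene list called in either line, with 1 bar per line. The p53 targets had the highest medians, 0.345 in A549 and 0.530 in H460, and homologous recombination genes the lowest in H460 at -0.373.

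With vehicle alone, A549 and H460 differed in 11752 of 16153 genes, 5957 higher and 5795 lower in A549 by edgeR's quasi-likelihood test. NNMT was at 121 ± 8.89 CPM in A549 and 1.58 ± 0.652 in H460, whereas MTAP, the methylthioadenosine phosphorylase, was at 0.397 ± 0.207 in A549 and 79.2 ± 2.25 in H460 (edgeR adjusted p = 4.76e-41 and 9.49e-41). Log2 fold changes of A549 over H460 were -1.86 for MYC, -4.99 for CD274, -0.92 for MDM4, -0.45 for E2F1, -0.44 for PRMT5 and -0.16 for MDM2, all lower in A549. CCND1 was higher by 1.63, CDKN1A by 0.74, KAT5 by 0.49 and MAT2A by 0.40. WDR77 at 0.14 and STK11 at 0.10 did not pass, and both passed with the filter of 10 CPM in 3 libraries. In all, STK11 passed in 2 of the alternatives and WDR77 in 1.

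CEACAM6, a cell adhesion glycoprotein, was at 412 ± 34.1 CPM in A549 and had no count in H460, at least 2224-fold higher against a floor of 3 counts per library. WNT7B was at least 1281-fold higher in A549, SLC22A3 at least 859.6-fold, ST6GAL2 at least 782-fold, the hepatocyte nuclear factor HNF4A at least 711-fold and HAVCR1 at least 658-fold. LINC00824 was at least 1959-fold lower in A549, SERPINB2 at least 768-fold, EPGN at least 604-fold and CDH13 at least 601-fold. The mesoderm factor TBXT had 3 counts in A549 and 73358 in H460 (ratio 25309, 95% interval 8660.1 to 122731), and EPB41L3 had 1 and 44468 (ratio 46026, 95% interval 8260.3 to 1817970), both exact binomial intervals.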

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

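Tests of library scaling, of p53 target levels, of carry-over, of the same-gene fit of 6 libraries and of GC content were chosen or written down only after the results they bear on had been seen. The first tests of library scaling and of GC content were replaced after their results had been seen. By the first GC test GC bias was argued against, and by the present one it stays open. The reading of the splits for genes changed the same way in both lines was also changed afterwards, from chance excluded to undecided. The first test of spread borrowed from the other line and the counts of other splits were written down before their values were computed, but after the treatment effects had been seen, and the fit of 6 libraries that the first of them reads had already been run. The value of that first test met the bound written down for borrowed spread. It was read as undecided afterwards, because its count filter had removed most of the genes, and the same-gene fit was then added.

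The effect of treatment differed between A549 and H460 for 1229 genes by the edgeR interaction test, and this difference between the lines brought in the genes and lists given here. Of 100 drawn splits of the treatment labels within each line, of 200 possible, 6 called as many genes with the real one included. The highest other split called 4917. It kept the true groups and exchanged only the H460 labels, so its contrast added the effects of both lines. All 5 other splits that called as many kept treated and vehicle H460 libraries apart, and so carried the whole H460 effect. The highest count among splits that mixed H460 libraries was 162. Such splits do not isolate the difference of effects, so this count neither excludes chance nor speaks for it. For the lists, 10 were called, and 19 of the 100 splits called as many, with 14 as the highest other.

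Lists with a different effect had limma camera adjusted p = 4.62e-09 for p53 targets, 5.71e-12 for DNA replication, 7.88e-05 for homologous recombination, 1.47e-05 for ribosome biogenesis and 4.58e-05 for glycolysis and hypoxia. The value was 0.00486 for ribosomal proteins, for cholesterol genes and for matrix genes, 0.0199 for NRF2 targets and 0.0197 for inflammatory genes. With an estimated correlation none of them kept its call (adjusted p = 0.133 to 0.901).

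A549 minus H460 log2 effects of p53 targets and apoptosis genes were -1.18 for GDF15, -0.91 for CDKN1A, -0.85 for PMAIP1, -0.73 for BTG2, -0.70 for ZMAT3, -0.50 for RRM2B, -0.48 for MDM2, -0.21 for TNFRSF10B and 0.29 for MCL1. Replication, repair and mitosis genes had 0.49 for FEN1, 0.53 for TYMS, 0.63 for RRM2, 0.69 for GINS4, 0.35 for E2F1, 0.32 for FANCI, 0.37 for FANCA, 0.37 for FANCG, 0.40 for BRCA1, 0.50 for BARD1, 0.36 for FOXM1 and -0.35 for AURKB. Ribosome, splicing and MYC-related genes had -0.34 for PRPF3, -0.24 for SF3B1, -0.21 for HNRNPA2B1, 0.30 for HNRNPF, 0.30 for SF3A2, 0.38 for RPL22, 0.24 for NOLC1, 0.25 for POLR1A, 0.34 for BOP1, 0.40 for GNL3 and 0.35 for MYC. Differences of matrix and inflammatory genes came to -0.91 for COL5A1, -0.60 for COL1A1, -0.86 for THBS1, -0.51 for TGFBI, 0.48 for CCN1, -0.62 for CXCL2, -0.56 for CXCL5, -0.43 for CXCL8, -0.39 for BIRC3 and 0.39 for TNFAIP2. RAS-MAPK output genes had -0.62 for PHLDA1, -0.43 for ETV1 and 0.33 for CCND1. Metabolic and antioxidant genes stood at -0.28 for AKR1B10, 0.21 for TXNRD1, 0.31 for GCLC, 0.53 for SRXN1, 0.55 for OSGIN1, -0.48 for PDK1, 0.33 for HK1, 0.29 for GPI, 1.27 for ADM, 0.27 for FDPS, 0.42 for IDI1 and 0.50 for HMGCS1. Other fixed or list genes showed 0.996 for NNMT and 0.30 for HLA-C. Genes with the largest changes in A549 by the fixed rule differed by 0.81 for PLEKHG6, 0.58 for SNHG3, 1.22 for ATP6V0C, 1.08 for MAP2, 0.83 for MAP3K14 and -0.35 for GGCX. Those with the largest changes in H460 by the same rule differed by -1.41 for HAPLN3, -0.62 for PTBP2, -1.10 for SH2D2A, -0.67 for SULF2, 1.25 for SFXN2, 1.20 for C3, 0.67 for DCAF16, 0.71 for HGH1 and 0.88 for MUC1. The fixed rule took the 6 highest and 6 lowest differences among genes with at least 10 CPM in the highest group, which are those of ADM and SFXN2 above and -4.78 for CES1, -2.97 for SYT13, -2.86 for PAK3, -2.23 for SUSD2, -1.62 for LINC01234, -1.52 for PAX6, 1.23 for LSR, 1.93 for CD38, 2.09 for CEACAM19 and 3.79 for FGA. CES1 had 0 counts in vehicle and 13 in treated H460, so its fitted value depends on the prior count, and FGA in H460 and PAK3 in A549 had 12 counts in vehicle and 1 after treatment. SYT13, SUSD2, CEACAM19, CD38 and LSR in H460 and PAX6 in A549 also had few counts. Calls lost without 1 library, with edgeR adjusted p, were those of GPI without H460 treated replicate 1 (0.0559), THBS1 without H460 treated replicate 3 (0.0991) and CXCL8 without A549 vehicle replicate 1 (0.0771). BARD1 was lost without H460 vehicle replicate 2 (0.0570), A549 vehicle replicate 1 (0.0505) or A549 treated replicate 2 (0.0658). FANCG was lost without H460 vehicle replicate 1 (0.0632) or 2 (0.119), H460 treated replicate 1 (0.0703) or 3 (0.102), A549 vehicle replicate 2 (0.0627) or 3 (0.100), or A549 treated replicate 2 (0.120). FDPS was lost without H460 vehicle replicate 2 (0.140), H460 treated replicate 1 (0.0924) or 2 (0.0587), A549 vehicle replicate 2 (0.0898), or A549 treated replicate 2 (0.0630) or 3 (0.0828). NNMT was lost without H460 vehicle replicate 1 (0.0514) or 3 (0.221) or treated replicate 3 (0.0887). Those of CES1, SUSD2 and PAK3 were lost without 4, 4 and 8 of the single libraries, at adjusted p up to 0.0662, 0.152 and 0.173. With other processing, calls were lost for CXCL8 (0.0630) and FANCG (0.0523) with the GC trend removed, for FANCG (0.0522) and PAK3 (0.0762) with no count filter, for PAK3 with DESeq2 (0.0903), and with limma voom for THBS1 (0.0689), FDPS (0.0503), CEACAM19 (0.0685), CES1 (0.0556), SUSD2 (0.286) and NNMT (0.216).

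Taken as lists, p53 targets rose less and replication genes fell less in A549, although not every replication gene fell there. These 2 differences were weighed against 2 technical explanations. Library scaling is argued against, since it cancels in the gap between the mean log2 CPM of the 2 lists within a library, and the treated minus vehicle change of this gap, replication minus p53, was 0.52 higher in A549. Its 9 values ran from -0.56 to -0.38 in A549 and from -1.03 to -0.94 in H460. A ceiling on p53 target levels stays open. Treated A549 was at or above treated H460 in 63.6% of the 11 targets (95% exact interval 30.8% to 89.1%). Which property of the lines underlies the difference was not tested.

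Large fold changes were called under 1 CPM in 46 genes of A549 and 105 of H460. Carry-over of an equal share of all RNAs from the other line is argued against. In each line, the 50 genes most abundant in the other were taken among those under 1% of their level there. They lay at a median of 0.196% of it, which is 0.0143 of the median share these calls would need, 13.7%. That share was taken over called genes with at least 1 CPM in the other line. The choice under 1% fixed the ratio to be small, so it measures no rate of carry-over. Yet an equal share of 13.7% would have lifted all genes, and these 50 in each line lay far below it. Spread borrowed from the other line cannot be told apart from a real change. In the 6 libraries of the line alone 21.9% were called, which met the bound written down for borrowed spread. Its count filter removed 112 of the 151 genes, however, and 33 of the 39 genes left were called. On the same genes as in the fit of 12 libraries, 55.6% were called (95% exact interval 47.3% to 63.7%).

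Genes lower in both lines had a median transcript GC content of 53.5% and genes higher in both 44.9%, with 48.7% among other genes. With each library's GC trend removed the medians were 49.8% and 48.0%, so 20.7% of the contrast was left. The removal takes away a GC contrast of any origin, so this share does not bear on its cause. GC bias between libraries stays open as the cause because of the slopes in A549. In A549 the slope of log2 CPM on 10 points of GC ranged by up to 0.060 within a group, against a treated minus vehicle difference of -0.025, and in H460 by up to 0.037 against -0.049. Of the 1427 shared calls 1243 were kept with the trend removed. No biological explanation was tested.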

How the results depend on the processing

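Removal of the GC trend, the restriction to expressed genes and lists without shared members were chosen after seeing the data. Counts of genes in the 4 contrasts and of genes changed the same way in both lines stayed within 1.5 times under DESeq2 size factors, the 2 count filters, DESeq2, limma voom, the fit of 6 libraries, GC removal and each library left out. The fit of 6 libraries gives no value for the difference. No called gene of the 4 contrasts turned to a call of the opposite sign in the settings compared. The equal replicate numbers were not taken as pairing (deviation correlations 0.126, 0.0133 and 0.0913 in A549, -0.00406, -0.00806 and -0.0426 in H460); with the replicate block, calls came to 1425 and 1468 in A549, 2100 and 2250 in H460, 685 and 558 in the difference and 5918 and 5753 at baseline. In A549 replicates 1 and 3, but not 2, correlated best with their own number. The share of mitochondrially encoded transcripts rose with the number in both A549 groups. It was 1.88%, 3.03% and 3.32% with vehicle and 1.81%, 2.88% and 3.17% with treatment. Pairing in A549 therefore stays undecided.

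Stricter thresholds lowered counts by construction. With an adjusted p under 0.01, genes higher and lower were 812 and 857 in A549, 1303 and 1499 in H460, and 335 and 256 in the difference. With an absolute log2 fold change of at least 1 they were 41 and 97, 170 and 197, 49 and 64, and 2938 and 2448 at baseline.

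For lists, an estimated correlation left 1 higher and 0 lower in A549, 2 and 1 in H460, and 0 and 0 in the difference. Without shared members the p53 and replication lists kept their calls. No count filter gave 9 higher in A549, and fry gave 5 lower in A549 and 3 higher in the difference. Leaving out 1 library gave 3 to 5 lower lists in A549 (5 without A549 vehicle replicate 3), 4 to 7 higher in the difference (4 without H460 vehicle replicate 2), and 69 to 104 genes in opposite directions, with 69 without A549 treated replicate 2. The cause was not tested.

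Signs turned only for uncalled values. In A549, E2F1 had 0.0013 with DESeq2 size factors, 0.0029 with no filter, 0.0012 with DESeq2, 0.0019 in 6 libraries and 0.050 with GC removed, CD274 0.036 with limma voom, and STK11 0.018 with GC removed. In H460 STK11 had 0.040 with GC removed. In the difference, WDR77 had -0.0062 and STK11 -0.0061 with 10 CPM in 3 libraries, STK11 -0.022 with GC removed, and MTAP 0.066 with limma voom. Over left-out libraries the ranges in A549 were -0.50 to 0.23 for MTAP, -0.049 to 0.035 for E2F1, -0.15 to 0.0084 for KAT5 and -0.53 to 0.49 for CD274. In H460 they were -0.13 to 0.0030 for WDR77 and -0.015 to 0.053 for CCND1, and in the difference -0.018 to 0.082 for PRMT5, -0.059 to 0.079 for WDR77, -0.0064 to 0.20 for MAT2A, -0.40 to 0.33 for MTAP and -0.018 to 0.027 for STK11. Their causes were not tested. Depth limits genes such as MTAP and CD274 in A549 and NNMT in H460.

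For 3 libraries against 3 the splits number 10, too few for a share under 0.05. Real and highest other counts were 2853 and 1 in A549, 4322 and 0 in H460, 11752 and 0 at baseline, and for lists 8 and 10 in A549, where 4 splits gave as many, and 14 and 12 in H460. Only the real one, 1 split, gave as many in each other case. For genes changed the same way in both lines, 1 of 100 splits, the real one, reached 1427, with 118 as the highest other. That other split kept the true groups and exchanged only the H460 labels, so its 118 genes are those of opposite direction under the real labels. The splits that mix libraries call almost no gene and so can share none, which leaves chance undecided for that overlap.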

Other observations

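The groups in this part were chosen after their values had been seen, and each test was written down afterwards, so every reading here is a hypothesis.

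Precursor mRNA processing factor genes of the PRPF family, 6 of which also stand in the spliceosome list, were called higher in 5 of 12 cases in A549 and in 8 of 12 in H460, with none lower. PRPF39 had log2 fold changes of 0.72 and 1.02, PRPF38B 0.38 and 0.96, and PRPF4B was called in H460 at 0.68. The family may rise beyond other genes in both lines, with limma camera p = 3.63e-06 in A549 and 9.75e-08 in H460, and p = 0.00890 and 0.00544 with an estimated correlation. Their signs were the same with DESeq2 size factors for all 12 genes in both lines. Such scaling moves all genes of a library alike, so the unchanged signs do not bear on the family against other genes.

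Of 32 collagen genes tested, 13 were called lower and 0 higher in A549, and 8 lower and 1 higher in H460. In A549 COL6A2 changed by -1.15, COL7A1 by -0.70 and COL6A1 by -0.55, and in H460 COL4A6 by -0.54, COL8A1 by -0.52 and COL6A1 by -0.44, whereas COL6A3 rose by 0.79 there on about 2.25 CPM in vehicle. The fall may be shared by the family in A549, with limma camera p = 1.23e-06, and p = 0.00382 with an estimated correlation. For H460 the values were 0.0266 and 0.141, so the family result there was lost with an estimated correlation. With DESeq2 size factors 31 of 32 signs were the same in each line, which likewise does not bear on the family against other genes.

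Antisense and divergent RNAs, named by their suffix, were lower in 32 and higher in 8 of 699 in A549, and lower in 77 and higher in 11 in H460. Protein-coding genes matched on mean CPM gave a median of 32 lower in A549, so the count did not exceed that of genes of like abundance (one-sided permutation test on 10000 matched sets, p = 0.518). In H460 the matched median was 48 and the highest draw 73, and the p of the same resampling test was 0.0001, the smallest these draws can give. Low abundance alone is argued against there only as far as genes vary independently. Each matched gene was drawn independently, so correlation between these RNAs could make the p too small. OIP5-AS1 fell by 0.23 in A549 and by 0.30 in H460. Of 72 tested host genes of the RNAs lower in H460, 13 were lower and 9 higher. Because the use of strand is not given, reads of host and antisense genes cannot be separated.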
